A study of Mus musculus with 24 samples.

How the data were processed

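RNA sequencing was performed on 24 libraries from sorted stem and progenitor cells of mouse bone marrow (the tissue field reads blood), in 8 groups of 3 libraries formed by genotype (WT or KO) and population (HSC, MPP1, MPP2 or MPP4). Groups and replicate numbers were taken from the titles. Per the labels, all animals had been given tamoxifen, total RNA was extracted with a column kit for small samples, and libraries were made with a kit whose strand setting the labels do not state. The deposited values were whole-number read counts per gene, not normalized, in 1 table with Ensembl gene identifiers and gene names. Per the submitters' processing notes, the mouse build was mm39 and SAMtools 1.12 and DESeq2 were used, with no role given for either. The aligner, the counting program, its annotation and its strand setting were not given in the sources used here. Each of the 24 columns was matched to a sample by the description field.

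Of 56748 genes in the table, 21964 passed edgeR's filterByExpr on the 8 groups. Total counts of 2540511 to 3807003 per library were scaled with the trimmed mean of M-values. One quasi-likelihood model with a mean per group was fitted to all 24 libraries (16 residual degrees of freedom, common biological coefficient of variation 0.393) in edgeR 4.0.16 under R 4.3.3. The 9 comparisons were KO against WT in each population, their average, the interaction of genotype and population (3 numerator degrees of freedom), and WT MPP1, MPP2 and MPP4 against WT HSC. All p-values were adjusted by Benjamini-Hochberg, and a gene was called at an adjusted p below 0.05. Fold changes are log2 values. Their standard error (SE) was derived from the test, as the absolute log2 fold change over the square root of the F statistic. Levels are CPM on the scaled totals, as mean ± SD of 3 libraries. Where a group had at most 3 counts in every library, levels are given in place of a fold. Whether those libraries are separate animals is not stated, so p-values measure only the spread between these samples, which may be technical.

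In all, 35 gene lists were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the first set of alternatives. Of these lists, 34 were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, and 1 had fewer than 5 measured genes and was not tested. P-values of lists were adjusted over the 34 lists of a comparison. Camera with an estimated correlation and fry were run beside it. The rule for named genes took Ddx6, up to 8 genes with the largest rise and 8 with the largest fall among called genes with a mean of at least 1 CPM and, in comparisons of 3 against 3 libraries, no overlap between the groups (for the average, the same sign in all 4 populations). It also took up to 4 members of each list described, those with the smallest p, the 8 genes with the smallest interaction p and, in WT comparisons, the sort markers. Predicted genes and clone names were passed over. Some genes that the rule takes are not reported here, though counts over named genes and lists include them. Other genes are said to have been chosen after their values were seen.

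Background was estimated after the data were examined, from 1760 olfactory and vomeronasal receptor genes. Their counts per kb of gene span in a library, times the span of each gene, gave the count expected from background. It was subtracted before a second fit of 18532 genes, with the differences rounded and values below 0 set to 0. Gene spans and chromosomes came from a reference annotation of the earlier build GRCm38, in which 52125 of the 56748 identifiers (91.9%) were found, and no coordinates are given. A name is shared with another gene by 959 genes. The code was tested on simulated data for KO against WT in HSC over 21964 genes. Of 100 genes changed 1.5-fold, 5 were recovered, and of 100 changed 3-fold, 33; among those of at least 20 CPM, 5 of 37 and 32 of 37 were. There were 5 unchanged genes among the calls (9.43%), and the median estimated folds were 1.53 and 2.77. A list of 23 genes lowered 2-fold had an adjusted p of 2.67e-25, and 0 of the other lists passed. With background as the only difference between genotypes, simulation over 24163 genes called 1626 rises and 1360 falls in HSC before subtraction, and 1 and 0 after it. The background subtracted there was the one that had been added. This checks the code and cannot show whether the estimate holds in the real libraries.

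The alternatives fixed beforehand were median-of-ratios size factors, no filter on low counts, a filter of at least 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with sample weights, a fit of only the 6 libraries compared, the replicate number as a block, each library left out in turn, and sums over the 4 populations. For lists they were an estimated correlation, fry, median-of-ratios size factors, a prior count of 0.5 and the block. Background subtraction, genes of at least 20 CPM, a test of folds above 1.5, an assumed biological coefficient of variation of 0.2 and sums of the 3 libraries of a group were added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.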

Results

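RNA was sequenced from blood stem and progenitor cells of mice in 24 libraries, 12 labelled wild type (WT) and 12 labelled knockout (KO), from animals given tamoxifen. In each genotype the libraries fell into 4 populations of 3 libraries each, namely haematopoietic stem cells (HSC) and the multipotent progenitor populations labelled MPP1, MPP2 and MPP4. The protocol gives bone marrow as the source of the sorted cells, although the tissue field reads blood. The total count per library ran from 2540511 to 3807003 in WT and from 2894916 to 3667509 in KO-labelled libraries. Of 56748 genes, 26856 to 30454 had at least 1 count in a WT library and 21477 to 25993 in a KO-labelled library. The 10 most abundant genes held 4.24 to 5.37% of the counts of a library and mitochondrially encoded genes 1.13 to 2.10%. The first principal component of log2 CPM (counts scaled to the total of the library) carried 30.7% of the variance and the second 9.38%. Libraries of a group differed by more than sampling noise, with a chi-square of 4.32 to 10.3 per gene between pairs, against 1 for counting error alone. The labels do not say whether the 3 libraries of a group came from separate mice, so every p-value measures only the spread between these libraries, which may be technical. Immunoglobulin V genes were at similar counts within groups: of 86 cases of a V gene with at least 50 counts in some library of a group, 85 were within 3-fold in all 3 libraries of that group.

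Genes of the olfactory and vomeronasal receptor families, which serve smell and are silent in blood cells, had counts in every library. They collected 4215 to 10046 counts in a WT library and 1951 to 6483 in a KO-labelled library. With their counts per kb of gene span taken as a background density, the share of all counts expected from background was 22.3 ± 1.64% in WT HSC (mean ± SD, n = 3) and 5.52 ± 0.175% in KO-labelled HSC. The shares were 23.9 ± 0.843% and 13.7 ± 0.278% in MPP1, 11.5 ± 0.202% and 9.32 ± 0.687% in MPP2-labelled libraries, and 30.4 ± 0.113% and 18.2 ± 0.306% in MPP4-labelled libraries. Genes above 64 CPM had a median log2 fold change of 0.53, 0.28, 0.07 and 0.35 between KO-labelled and WT libraries of HSC, MPP1, MPP2 and MPP4, and genes below 8 CPM of -1.78, -0.60, -0.45 and -0.63. With genes of at most 3 counts in every library of a group set to the value of 3 counts per library, the medians below 8 CPM were -1.17, -0.56, -0.27 and -0.61. For this reason the counts of called genes are given both as deposited and after this background was subtracted. A call lost after subtraction is not by itself owed to background, as p-values also rose for genes with little of it. Background was 0.41% of the WT count of Mpo and 0.12% of that of Ighm. Their adjusted p in edgeR's interaction test went from 1.43e-23 to 1.355e-12 and from 1.26e-19 to 5.65e-10.

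**Figure D1:**
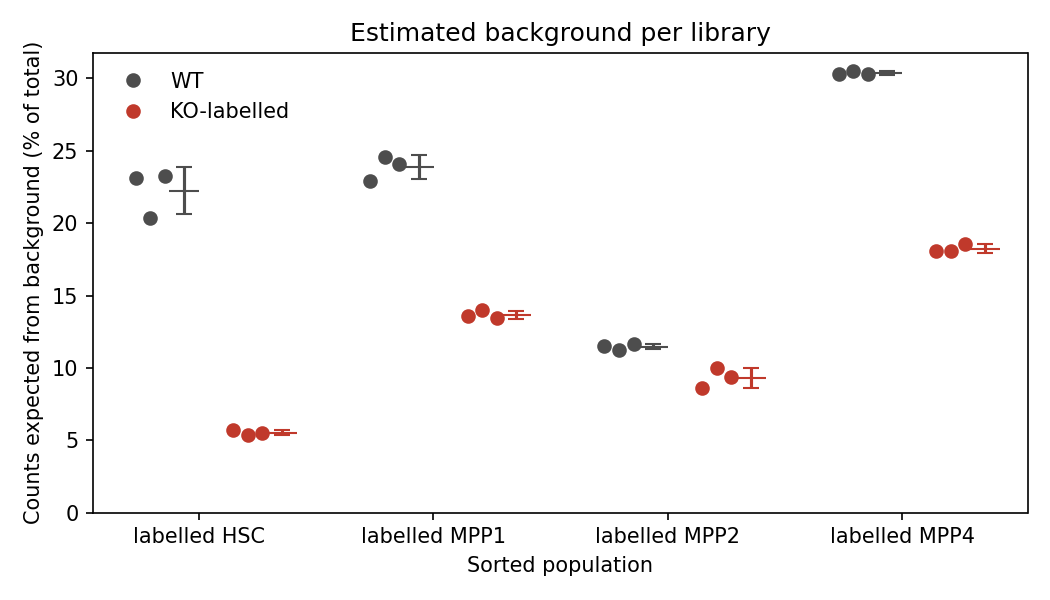
Share of the total count expected from background (percent, y axis) in each of the 24 libraries, by sorted population and genotype; points are libraries, lines and bars the mean and SD of 3. WT libraries ran from 11.2 to 30.5% and KO-labelled libraries from 5.36 to 18.6%.

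The labels do not name the gene that was knocked out. Ddx6 (ENSMUSG00000032097.11), an RNA helicase needed for P-body assembly, was taken as the target from general knowledge of the study, not from the labels, and was examined first. P-bodies are cytoplasmic granules of RNA and of proteins that repress translation and decay RNA. Ddx6 had 154 to 319 counts in the WT libraries and 194 to 308 in the KO-labelled libraries. Its log2 fold change was 0.29 ± 0.18 (SE, n = 3 against 3) in HSC, 0.61 ± 0.18 in MPP1, 0.11 ± 0.18 in MPP2-labelled and 0.29 ± 0.19 in MPP4-labelled libraries, with adjusted p of 0.199, 0.0211, 0.795 and 0.308 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Averaged over the 4 populations it was higher by 0.32 ± 0.09 (adjusted p = 0.00355), and after background subtraction the average was 0.05. After subtraction the estimate was -0.15 in HSC and -0.03 in MPP2-labelled libraries, so its sign depended on the background there. The call in MPP1 was lost with median-of-ratios size factors (adjusted p = 0.0637), after subtraction (0.296) and without WT replicate 2, KO-labelled replicate 1 or KO-labelled replicate 2 (0.185, 0.106 and 0.0503), and that of the average with these size factors (0.0526) and after subtraction (0.752). Both were lost also among genes of at least 20 CPM (0.155 and 0.455), and that of the average with the 3 libraries of a group summed (0.147). Counts per gene include reads outside any deleted exon, so they neither show nor exclude a deletion. Because Ddx6 RNA was not lower in them, these libraries are called KO-labelled throughout, and every direction rests on that label.

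The comparison within HSC asks how RNA differed between KO-labelled and WT cells sorted as normal stem cells, in a study of RNA held in P-bodies in myeloid leukemia. RNA of sort markers differed too, in both directions. Slamf1 was at 73.4 to 82.1 CPM of the unscaled total in WT and 190 to 243 in KO-labelled HSC. Procr was at 49.9 to 75.5 and 16.7 to 21.7. These genes were chosen after their values were seen. Whether the mix of sorted cells differed between genotypes was not tested. Immediate early genes, which signals and stress switch on within minutes, were lower in KO-labelled HSC: 1 of 23 measured genes rose, 16 fell and 6 were not called, against 1 and 16 adjusted over the list alone and 1 and 13 after background subtraction. Egr1, a transcription factor linked to stem cell quiescence, was 4.61-fold lower (log2 fold change -2.20 ± 0.18, adjusted p = 1.42e-13, edgeR), and the activator protein genes Jun and Fosb changed by -3.22 ± 0.29 and -1.75 ± 0.13. The 1 gene of the list that rose was Myc, a driver of cell growth, at 2.08 ± 0.12 (adjusted p = 1.66e-17). The list as a whole was lower (camera, adjusted p = 1.22e-04 over the 34 lists tested). Of the 51 list results given with camera for the comparisons in this part, 50 stayed on the same side of the threshold with an estimated correlation between genes. The exception was G2 and mitosis in MPP1. Lists given later under other observations are not among the 51, and there the mitochondrially encoded proteins in HSC lost their call too. With the estimated correlation, the number of all tested lists past the threshold went from 24 to 23 in HSC, 17 to 11 in MPP1 and 24 to 20 in MPP4-labelled libraries, and stayed at 17 in MPP2-labelled libraries.

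Genes of DNA replication and mitosis were higher. Among S phase genes, 23 of 29 measured genes rose and 6 were not called, with 23 rises adjusted over the list alone and 11 after background subtraction. Pola1, the catalytic subunit of DNA polymerase alpha, changed by 1.45 ± 0.10, the helicase subunit Mcm5 by 1.47 ± 0.14 and Dtl by 1.64 ± 0.16. Among genes of G2 and mitosis, 20 of 30 measured genes rose and 10 were not called, with 22 rises adjusted over the list alone and 8 after background subtraction. The proliferation marker Mki67 changed by 1.37 ± 0.07, the mitotic kinase Plk1 by 1.94 ± 0.16 and the topoisomerase Top2a by 1.37 ± 0.14. Both lists were higher than other genes (camera, adjusted p = 1.1e-10 and 1.79e-10). In cholesterol synthesis, 8 of 24 measured genes rose and 16 were not called, with 8 rises adjusted over the list alone and 3 after background subtraction (camera, adjusted p = 2.75e-05), among them the squalene epoxidase Sqle (2.08 ± 0.23) and the squalene synthase Fdft1 (1.44 ± 0.24).

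Other broad groups were also higher in KO-labelled HSC, with fewer calls once background was subtracted. Of the nuclear genes of oxidative phosphorylation, 27 of 80 measured genes rose, 1 fell and 52 were not called, against 27 and 1 adjusted over the list alone and 5 and 0 after background subtraction (camera, adjusted p = 8.07e-09). Sdhc of complex II changed by 1.19 ± 0.12 and cytochrome c1, Cyc1, was 2.84-fold higher. Of chromatin regulators, 48 of 63 measured genes rose, 1 fell and 14 were not called, against 51 and 1 adjusted over the list alone and 12 and 2 after background subtraction (adjusted p = 3.41e-14). Of its SWI/SNF subunits, Smarcc1 was at 1.14 ± 0.08, Arid1b at 0.92 ± 0.06 and Smarca4 at 1.04 ± 0.09. Of type I interferon response genes, 15 of 37 measured genes rose and 22 were not called, with 14 rises adjusted over the list alone and 3 after background subtraction (adjusted p = 6.7e-06). Ly6e was 2.17-fold higher and the antiviral synthetase Oas2 changed by 1.78 ± 0.16. Of P-body components, 15 of 33 measured genes rose, 2 fell and 16 were not called, against 15 and 2 adjusted over the list alone and 4 and 1 after background subtraction (adjusted p = 6.7e-06). The cap-binding protein Eif4e changed by 1.33 ± 0.12, the decapping cofactor Pnrc2 by 1.42 ± 0.23, and the RNA-binding Mex3a was 2.83-fold higher. With only genes of at least 20 CPM, the interferon and P-body lists were no longer past the threshold (adjusted p = 0.0621 for both). Markers of cells outside the sort were lower as deposited, with 13 of 18 stromal and endothelial genes and 8 of 21 mature lymphocyte genes falling (13 and 8 adjusted over the list alone), against 0 and 1 after subtraction.

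The largest changes in HSC were mostly of genes near the detection limit. All 8 genes of the largest falls had no count in 1 group, among them Pax6, a transcription factor of the eye and brain, at 10.6 ± 8.94 CPM (mean ± SD, n = 3) in WT and 0 ± 0 in KO-labelled HSC, and the niche chemokine Cxcl12 at 8.16 ± 4.38 and 0 ± 0. After background subtraction 1 of the 8 was still called and 1 was not tested, and the adjusted p was 0.0996 for Pax6 and 0.056 for Cxcl12. The acetylcholinesterase gene Ache, a named rise above this floor, went from 11.9 ± 1.43 to 125 ± 19.7 CPM, a log2 fold change of 3.39 ± 0.33 (adjusted p = 2.99e-11, edgeR). The metallothionein Mt1 had 0.0952 ± 0.165 CPM in WT and 6.72 ± 2.25 in KO-labelled HSC. Across the table, 4012 of 21964 tested genes rose and 5450 fell by edgeR at a false discovery rate of 0.05, the highest count of the 4 populations. After background subtraction there were 827 rises and 770 falls among 18532 genes, and 7 of the calls as deposited were called in the opposite direction. KO-labelled and WT HSC also differed most in background share, and the median of all genes was -0.31 as deposited (-0.24 with groups of at most 3 counts set to 3), -0.46 with median-of-ratios size factors and -0.19 after subtraction.

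In MPP1, genes of red cell formation were lower in the KO-labelled libraries: 18 of 23 measured erythroid genes fell and 5 were not called, with 21 falls adjusted over the list alone and 19 after background subtraction (camera, adjusted p = 8.78e-25). The red cell carbonic anhydrase Car1 was 10.9-fold lower (log2 fold change -3.44 ± 0.20, SE, n = 3 against 3, adjusted p = 3.68e-17, edgeR), the globin genes Hbb-bs and Hba-a1 changed by -2.98 ± 0.18 and -3.51 ± 0.29, and the red cell anion exchanger Slc4a1 by -2.80 ± 0.22. Globin genes held 0.0308 ± 0.000944% of the counts in WT MPP1 (mean ± SD, n = 3) and 0.00319 ± 0.000259% in KO-labelled MPP1. Lymphoid genes went the other way: 12 of 19 measured genes of lymphoid priming rose and 7 were not called, with 13 rises adjusted over the list alone and 8 after background subtraction (adjusted p = 9.63e-08). Among them were Ighm, the heavy chain constant region of IgM, at 3.35 ± 0.13, the template-free DNA polymerase Dntt at 2.27 ± 0.22 and the interleukin receptor Il7r at 3.30 ± 0.38.

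Immediate early genes were lower in MPP1 too: 2 of 23 measured genes rose, 13 fell and 8 were not called, against 2 and 15 adjusted over the list alone and 2 and 11 after background subtraction (camera, adjusted p = 1.53e-10). Egr1 changed by -2.95 ± 0.19, Jun by -3.75 ± 0.31 and Fosb by -1.80 ± 0.13, while Myc rose by 1.66 ± 0.12. Of genes of glycolysis and hypoxia, 9 of 27 measured genes rose and 18 were not called, with 15 rises adjusted over the list alone and 3 after background subtraction (adjusted p = 3.48e-06). Glucose phosphate isomerase, Gpi1, was at 0.95 ± 0.10 and pyruvate kinase, Pkm, at 1.26 ± 0.15. Of cholesterol genes, 8 of 24 measured genes rose and 16 were not called, with 9 rises adjusted over the list alone and 4 after background subtraction (adjusted p = 4.77e-05). The transcription factor Srebf2 was at 0.82 ± 0.10. Of P-body components, 8 of 33 measured genes rose, 1 fell and 24 were not called, against 9 and 1 adjusted over the list alone and 4 and 1 after background subtraction (adjusted p = 4.77e-05). Mex3a was at 1.75 ± 0.19 and Tnrc6a, a scaffold of microRNA silencing, at 0.78 ± 0.15. Of genes of G2 and mitosis, 7 of 30 measured genes fell and 23 were not called, with 8 falls adjusted over the list alone and 7 after background subtraction. Cyclin A2, Ccna2, changed by -1.12 ± 0.24 and Mki67 by -0.30 ± 0.07. That last list had an adjusted p of 0.0081 by camera with its preset correlation, and an adjusted p = 0.0627 with an estimated correlation.

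The largest rises in MPP1 included immunoglobulin V segments, with Ighv7-1 at 0.856 ± 0.558 CPM in WT and 147 ± 16.7 in KO-labelled libraries, and the chemokine Ccl9 at 1.34 ± 0.326 and 36 ± 3.39. The granule enzyme myeloperoxidase, Mpo, went from 132 ± 19.5 to 5.14 ± 0.829 CPM (-4.67 ± 0.18). It was picked for its abundance after its values were seen. In MPP1 as a whole, 1912 of 21964 tested genes rose and 1076 fell, and after subtraction there were 606 rises and 513 falls among 18532 genes. The split depended on the scaling: rises were 1912 of 2988 calls with the trimmed mean of M-values. They were 52.2% of the calls with median-of-ratios size factors (1421 against 1300) and 49.5% with DESeq2 (1679 against 1711). Each of the 8 largest falls in MPP1 had a group with no count, so no fold is given for them.

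In the MPP2-labelled libraries, immediate early genes were lower: 1 of 23 measured genes rose, 17 fell and 5 were not called, against 1 and 19 adjusted over the list alone and 1 and 13 after background subtraction (camera, adjusted p = 4.33e-22). Egr1 was 16-fold lower (n = 3 against 3, adjusted p = 8.75e-20, edgeR), the antiproliferative gene Btg2 changed by -3.57 ± 0.32 and the phosphatase gene Dusp1 by -2.29 ± 0.23. Markers of mast cells, basophils and eosinophils were higher: 7 of 14 measured genes rose and 7 were not called, with 8 rises adjusted over the list alone and 4 after background subtraction (adjusted p = 2.1e-10). Il1rl1, an interleukin receptor of mast cells and other innate cells, was 15.4-fold higher (3.94 ± 0.23, adjusted p = 3.42e-17), the mast cell carboxypeptidase Cpa3 changed by 2.14 ± 0.30 and Ms4a2, the beta chain of the IgE receptor, by 2.41 ± 0.48. Erythroid genes were lower, where 8 of 23 measured genes fell and 15 were not called, with 9 falls adjusted over the list alone and 8 after background subtraction (adjusted p = 3.24e-06). The carbonic anhydrase Car2 changed by -1.97 ± 0.20 and the water channel Aqp1 by -3.89 ± 0.49 (-4.53 without KO-labelled replicate 3).

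Among genes of cholesterol synthesis in these libraries, 4 of 24 measured genes rose and 20 were not called, with 7 rises adjusted over the list alone and 3 after background subtraction (camera, adjusted p = 1.02e-06). Sqle was at 1.57 ± 0.23. Genes of the unfolded protein and integrated stress responses were higher: 8 of 33 measured genes rose, 1 fell and 24 were not called, against 8 and 2 adjusted over the list alone and 5 and 0 after background subtraction (adjusted p = 3.24e-06). They included Xbp1, a transcription factor of the endoplasmic reticulum stress response, at 1.31 ± 0.20, the chaperone gene Calr at 0.79 ± 0.08 and the amino acid transporter subunit Slc7a5 at 1.33 ± 0.24. Stem cell identity genes were lower on balance, as 3 of 27 measured genes rose, 7 fell and 17 were not called, against 4 and 10 adjusted over the list alone and 2 and 7 after background subtraction (adjusted p = 0.0458). Meis1 changed by -0.66 ± 0.06, while Mecom rose by 0.66 ± 0.06. The call of the list was lost with a prior count of 0.5 (adjusted p = 0.0552), with the replicate number as a block (0.0965), and without WT replicate 3, KO-labelled replicate 1 or KO-labelled replicate 2 (0.0674, 0.0699 and 0.0817). Of P-body components, 3 of 33 measured genes rose, 1 fell and 29 were not called, against 4 and 2 adjusted over the list alone and 2 and 1 after background subtraction (adjusted p = 0.0458), a call that was lost with median-of-ratios size factors, after background subtraction, with genes of at least 20 CPM, and without any single library other than KO-labelled replicate 3 (adjusted p of 0.0516 to 0.111 in these 5 fits). Zfp36, which marks AU-rich RNAs for decay, changed by -2.54 ± 0.30 and Zfp36l1 by 1.22 ± 0.24.

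All 8 of the largest rises in the MPP2-labelled libraries were immunoglobulin V segments, among them Ighv3-5 at 0.306 ± 0.0162 CPM in WT and 709 ± 16.7 in KO-labelled libraries, and Igkv4-68 at 0 ± 0 and 201 ± 10.5. V segments belong to families of similar sequence, so their counts can be split between copies, and their folds are not given. Ighm went from 947 ± 73.4 to 8366 ± 242 CPM, and immunoglobulin genes together held 0.144 ± 0.00566% of the counts in WT and 1.42 ± 0.0478% in KO-labelled libraries (mean ± SD, n = 3). Counts per library do not show which of the sorted cells held immunoglobulin RNA, in these or the other populations. Whether it came from the progenitors or from other cells in the sort was not tested. In the MPP2-labelled libraries, 820 of 21964 tested genes rose and 915 fell, and after subtraction there were 296 rises and 565 falls among 18532 genes. Leaving out WT replicate 3 gave 1117 called genes in place of 1735.

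In the MPP4-labelled libraries, genes of granulocyte and monocyte progenitors were higher in the KO-labelled group: 11 of 21 measured genes rose, 1 fell and 9 were not called, against 13 and 1 adjusted over the list alone and 7 and 1 after background subtraction (camera, adjusted p = 6.4e-07). Csf2rb, the shared chain of several myeloid cytokine receptors, was 5.16-fold higher (log2 fold change 2.37 ± 0.16, SE, n = 3 against 3, adjusted p = 2.49e-15, edgeR), Mpo changed by 1.47 ± 0.12 and the myeloid transcription factor gene Spi1 by 1.61 ± 0.17. Calr, which encodes a chaperone of the endoplasmic reticulum rather than a lineage product, changed by 1.61 ± 0.08. Erythroid genes were lower, and 12 of 23 measured genes fell and 11 were not called, with 13 falls adjusted over the list alone and 14 after background subtraction (adjusted p = 1.13e-06). Hbb-bs changed by -1.36 ± 0.17, Car1 by -1.24 ± 0.17 and Ermap, a red cell membrane protein, by -1.49 ± 0.26. Globin genes held 0.0342 ± 0.00191% of the counts in WT (mean ± SD, n = 3) and 0.0115 ± 0.00145% in KO-labelled libraries. Of immediate early genes, 1 of 23 measured genes rose, 10 fell and 12 were not called, against 2 and 15 adjusted over the list alone and 0 and 10 after background subtraction (adjusted p = 1.82e-06). Egr1 was at -3.09 ± 0.20 and Jun at -2.64 ± 0.29.

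Lists of metabolic and cell cycle genes were also higher by camera in these libraries, though most members of each were not called. Of genes of glycolysis and hypoxia, 11 of 27 measured genes rose and 16 were not called, with 13 rises adjusted over the list alone and 8 after background subtraction (camera, adjusted p = 2.01e-06). Gapdh was at 1.22 ± 0.10, Pkm at 1.47 ± 0.16 and the aldolase Aldoa at 1.31 ± 0.20. Of cholesterol genes, 9 of 24 measured genes rose and 15 were not called, with 10 rises adjusted over the list alone and 5 after background subtraction (adjusted p = 3.89e-06). Srebf2 was at 1.08 ± 0.10, Sqle at 1.65 ± 0.23 and Nsdhl at 1.53 ± 0.30. Of genes of G2 and mitosis, 9 of 30 measured genes rose and 21 were not called, with 13 rises adjusted over the list alone and 2 after background subtraction (adjusted p = 8.55e-07). The mitotic kinase Aurka was at 1.57 ± 0.23 and Top2a at 0.96 ± 0.14. Of P-body components, 10 of 33 measured genes rose, 1 fell and 22 were not called, against 12 and 1 adjusted over the list alone and 4 and 0 after background subtraction (adjusted p = 4e-05). Mex3a was at 1.28 ± 0.19, Tnrc6a at 0.89 ± 0.15 and Eif4e at 0.76 ± 0.12. That call was lost with genes of at least 20 CPM (adjusted p = 0.0771). Of stromal and endothelial markers, 3 of 18 measured genes fell and 15 were not called, with 3 falls adjusted over the list alone and 0 after background subtraction. V segments moved both ways, with Ighv11-2 at 1.52 ± 1.53 CPM in WT and 422 ± 31 in KO-labelled libraries and Ighv5-16 at 134 ± 10.1 and 0.512 ± 0.645. In the MPP4-labelled libraries, 2506 of 21964 tested genes rose and 1420 fell, and after subtraction there were 827 rises and 518 falls among 18532 genes. Rises were 63.8% of the calls as deposited, 44.1% with median-of-ratios size factors (1521 against 1927) and 41.8% with DESeq2 (1780 against 2474), and the median of all genes was -0.08 and -0.24 under the first and the second.

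**Figure D2:**
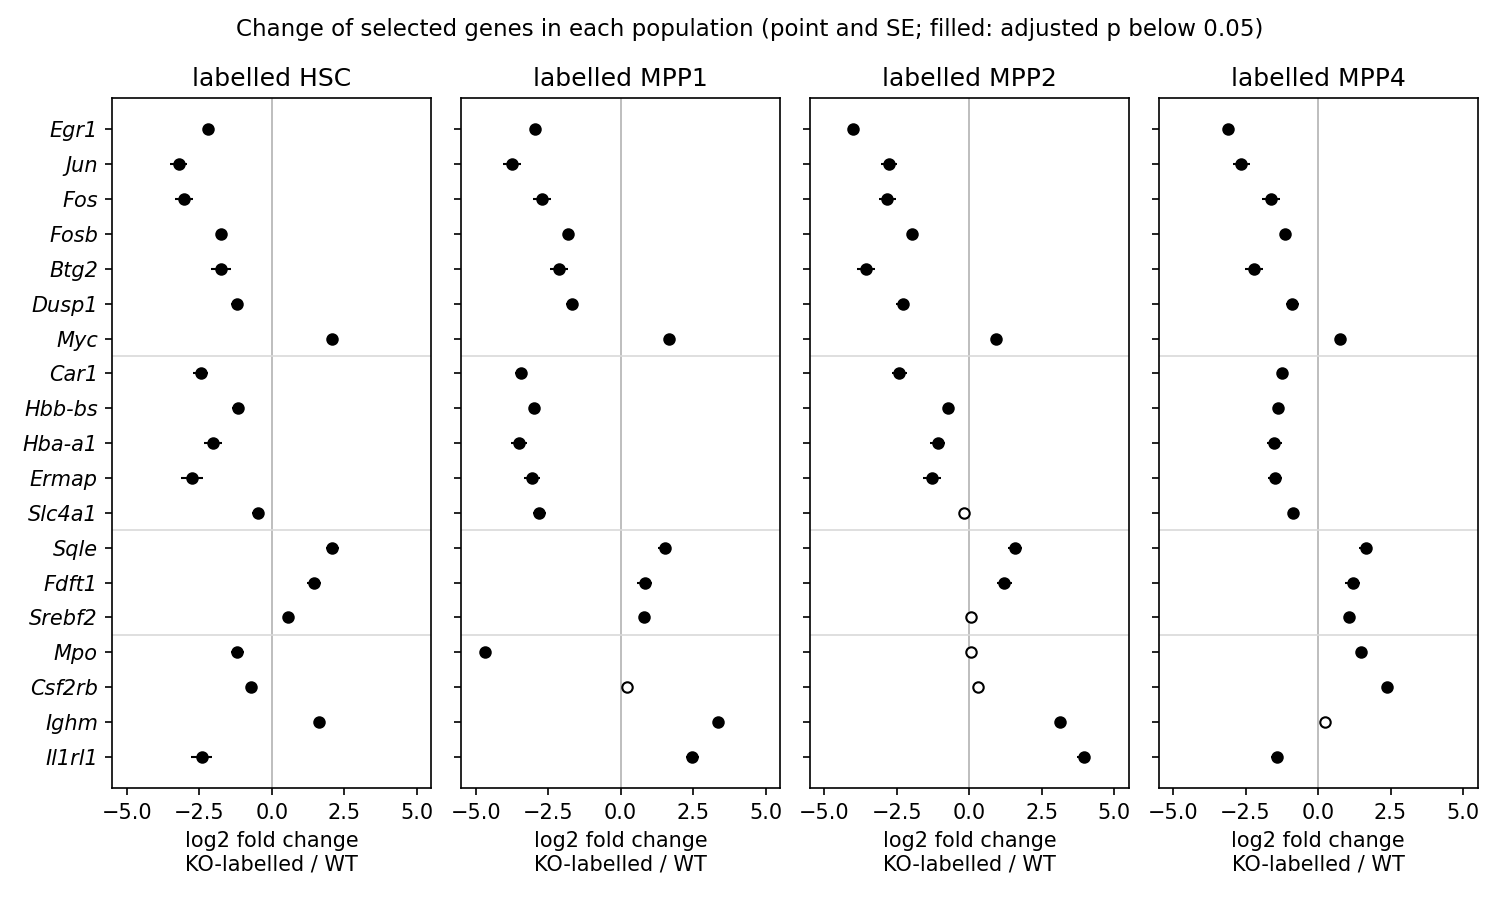
Log2 fold change between KO-labelled and WT libraries (x axis) of 19 genes in each population, with its standard error as a bar; filled points had an adjusted p below 0.05 (edgeR, 3 libraries against 3). Sqle was at 2.08 ± 0.23, 1.53 ± 0.23, 1.57 ± 0.23 and 1.65 ± 0.23 in HSC, MPP1, MPP2 and MPP4, while Egr1 was lower in all 4; genes outside the named set in a population were chosen after their values were seen.

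Averaged over the 4 populations, the comparison asks for the mean change in the KO-labelled libraries, which not all 4 need share. Immediate early genes were lower: 1 of 23 measured genes rose, 19 fell and 3 were not called, against 1 and 19 adjusted over the list alone and 1 and 19 after background subtraction (camera, adjusted p = 1.8e-08), with Egr1 at a mean log2 fold change of -3.06 ± 0.09 (SE, 12 libraries against 12, adjusted p = 2.33e-27, edgeR), Jun at -3.09 ± 0.15 and Fosb at -1.66 ± 0.07, against a rise of Myc by 1.35 ± 0.06. Erythroid genes were lower as well, as 1 of 23 measured genes rose, 15 fell and 7 were not called, against 1 and 15 adjusted over the list alone and 0 and 16 after background subtraction (adjusted p = 7.61e-07). Car1 was at -2.39 ± 0.11 and Hba-a1 at -2.03 ± 0.14. Cholesterol synthesis was higher: 16 of 24 measured genes rose and 8 were not called, with 16 rises adjusted over the list alone and 9 after background subtraction (adjusted p = 4.23e-07). Sqle was at 1.71 ± 0.11. Of genes of glycolysis and hypoxia, 16 of 27 measured genes rose and 11 were not called, with 16 rises adjusted over the list alone and 12 after background subtraction (adjusted p = 2.57e-07). Gapdh was at 0.85 ± 0.05 and lactate dehydrogenase, Ldha, at 0.91 ± 0.09.

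In the average, 36 of 80 measured nuclear genes of oxidative phosphorylation rose, 1 fell and 43 were not called, against 34 and 1 adjusted over the list alone and 9 and 0 after background subtraction (camera, adjusted p = 1.61e-08). Sdhc was at 0.83 ± 0.06. Of chromatin regulators, 53 of 63 measured genes rose, 1 fell and 9 were not called, against 53 and 1 adjusted over the list alone and 18 and 2 after background subtraction (adjusted p = 9.49e-16). Smarcc1 was at 0.82 ± 0.04 and the DNA demethylase Tet2 at 0.73 ± 0.05. Of P-body components, 22 of 33 measured genes rose, 2 fell and 9 were not called, against 22 and 2 adjusted over the list alone and 8 and 1 after background subtraction (adjusted p = 3.18e-06). Mex3a was at 1.27 ± 0.09, Eif4e at 0.75 ± 0.06 and, in the other direction, Zfp36 at -1.42 ± 0.15. Among the largest rises, the myosin light chain gene Myl10 was at 3.23 ± 0.33 and the chemokine Ccl9 at 2.98 ± 0.27 (adjusted p = 9.92e-11 and 3.48e-12). In total, 5034 of 21964 tested genes rose and 6655 fell, and after subtraction there were 1777 rises and 2596 falls among 18532 genes. Which direction had more calls depended on the fit: sums over the 4 populations per genotype and replicate number gave 5459 rises and 4663 falls. With the 3 libraries of each group summed and population as a block, 2146 genes were called (1106 rises and 1040 falls), of which 2144 were also called in the fit of 24 libraries. The median of all genes was -0.22, and -0.33 with median-of-ratios size factors.

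Some genes were called in the same direction in all 4 populations, whose libraries are not shared between the comparisons. There were 313 such rises, where independent lists of these sizes would share 1.49, and 135 such falls, where they would share 0.719. After background subtraction, 47 rises and 55 falls were shared, against 0.0193 and 0.0182. These reference numbers take every gene as equally likely to be called. Yet as deposited the median of genes above 64 CPM was higher, and that of genes below 8 CPM lower, in all 4 comparisons. The background share was lower in the KO-labelled libraries of all 4. Whether the populations came from the same mice is not stated, so the excess does not measure a shared effect of genotype. Egr1, Jun and Fosb were among the falls and Sqle among the rises in each of the 4.

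Whether the difference between genotypes itself differed between populations was tested with an interaction term. Mpo had the lowest adjusted p after the V segment Ighv5-16 (adjusted p = 1.43e-23, edgeR): its log2 fold change was -1.19 ± 0.23 in HSC, -4.67 ± 0.18 in MPP1, 0.05 ± 0.12 in MPP2-labelled and 1.47 ± 0.12 in MPP4-labelled libraries. Ighm (adjusted p = 1.26e-19) was at 1.63 ± 0.19, 3.35 ± 0.13, 3.14 ± 0.11 and 0.25 ± 0.10 in the same order. The lipid phosphatase gene Inpp4b (adjusted p = 5.59e-20) was at 0.37 ± 0.11, 1.35 ± 0.11, 2.77 ± 0.11 and -0.55 ± 0.11. Its call in HSC was lost without KO-labelled replicate 2 or WT replicate 2 (adjusted p = 0.0532 and 0.0836). In total 3881 of 21964 genes had an interaction at a false discovery rate of 0.05, and 1129 of 18532 after background subtraction. Set against the difference in HSC, the difference in MPP1 was higher for 1351 genes and lower for 860, that in MPP2 higher for 2085 and lower for 1740, and that in MPP4 higher for 1294 and lower for 626. After subtraction these counts were 209 and 350, 201 and 349, and 253 and 233, so the direction of the first and the second turned with the background. All 3 use the HSC libraries.

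The WT populations were compared with WT HSC to describe what set the labelled populations apart without the knockout. All 3 comparisons share the WT HSC libraries, so their lists of genes are not independent of each other. In WT MPP1, erythroid genes were higher than in HSC: 17 of 23 measured genes rose, 1 fell and 5 were not called, against 21 and 1 adjusted over the list alone and 12 and 1 after background subtraction (camera, adjusted p = 8.07e-30). Car1 was 8.3-fold higher (log2 fold change 3.05 ± 0.19, SE, n = 3 against 3, adjusted p = 1.04e-15, edgeR), and Ermap and Hbb-bs changed by 3.35 ± 0.28 and 1.86 ± 0.17. Stem cell identity genes were lower, and 0 of 27 measured genes rose, 14 fell and 13 were not called, against 2 and 18 adjusted over the list alone and 1 and 7 after background subtraction (adjusted p = 6.37e-16). The transcription factor Gata2 was at -2.03 ± 0.17 and the von Willebrand factor gene Vwf at -1.51 ± 0.17. Of megakaryocyte and platelet genes, 0 of 19 measured genes rose, 9 fell and 10 were not called, against 1 and 13 adjusted over the list alone and 0 and 9 after background subtraction (adjusted p = 5.73e-12). Fli1 was at -0.51 ± 0.06 and Nfe2 at -0.77 ± 0.14. Of cytosolic ribosomal protein genes, 13 of 75 measured genes rose, 0 fell and 62 were not called, against 22 and 1 adjusted over the list alone and 16 and 0 after background subtraction (adjusted p = 1.47e-17). Rpl41 was at 1.04 ± 0.18 and Rps2 at 0.75 ± 0.13. These genes have many processed pseudogenes, so their counts are uncertain. Of S phase genes, 6 of 29 measured genes rose and 23 were not called, with 10 rises adjusted over the list alone and 8 after background subtraction (adjusted p = 6.13e-08). Pola1 was at 0.77 ± 0.10.

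Among markers commonly used to sort such cells, which check the labels and are no finding, Flt3 was higher in WT MPP1 than in HSC by 2.74 ± 0.12, Cd34 by 1.28 ± 0.19 and Cd48 by 1.30 ± 0.35, and Slamf1 changed by -2.90 ± 0.38 and Kit by -0.32 ± 0.08. Without WT MPP1 replicate 2 the value of Slamf1 was -4.02, and Kit and Cd48 lost their calls (adjusted p = 0.0517 and 0.162). Cd48 lost its call also without WT HSC replicate 1 or 3 (0.0504 and 0.203), with limma-voom (0.146) and in a fit of the 6 libraries alone (0.138). Il7r, Procr, Fcgr3 and Ly6a were not called (log2 fold changes of 0.41 ± 0.44, -0.53 ± 0.36, 1.38 ± 0.68 and 0.17 ± 0.24), though Il7r was called after background subtraction (adjusted p = 0.0447). The stress gene Nupr1 was the largest fall, from 161 ± 11.3 CPM in HSC to 12.2 ± 4.01 in MPP1, and Mpo a large rise at 3.51 ± 0.15. In WT MPP1 against HSC, 433 of 21964 tested genes rose and 402 fell, and after subtraction there were 498 rises and 321 falls among 18532 genes.

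In the WT libraries labelled MPP2, lymphoid genes were higher than in HSC: 15 of 19 measured genes of lymphoid priming rose and 4 were not called, with 16 rises adjusted over the list alone and 12 after background subtraction (camera, adjusted p = 9.51e-20). Flt3, the cytokine receptor of lymphoid-primed progenitors and a sort marker, was 18-fold higher (log2 fold change 4.17 ± 0.13, SE, n = 3 against 3, adjusted p = 1.42e-27, edgeR), and Ighm and the chromatin organiser Satb1 changed by 7.20 ± 0.16 and 4.64 ± 0.18. Of granulocyte and monocyte progenitor genes, 18 of 21 measured genes rose and 3 were not called, with 18 rises adjusted over the list alone and 12 after background subtraction (adjusted p = 9.51e-20). Mpo was at 7.05 ± 0.16 and the neutrophil elastase Elane at 7.12 ± 0.45 (9.96 without WT HSC replicate 3). Of stem cell identity genes, 19 of 27 measured genes fell and 8 were not called, with 21 falls adjusted over the list alone and 17 after background subtraction (adjusted p = 3.01e-16). The ion channel Trpc6 was at -3.50 ± 0.17 and Mecom at -0.89 ± 0.06. Of megakaryocyte and platelet genes, 1 of 19 measured genes rose, 13 fell and 5 were not called, against 1 and 14 adjusted over the list alone and 1 and 12 after background subtraction (adjusted p = 1.48e-08). Vwf was at -2.59 ± 0.19 and, higher, Plek at 1.40 ± 0.18. Of genes of G2 and mitosis, 26 of 30 measured genes rose and 4 were not called, with 26 rises adjusted over the list alone and 20 after background subtraction (adjusted p = 1.7e-21). Mki67 was at 1.63 ± 0.07 and Plk1 at 2.11 ± 0.16.

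Of the other sort markers in the MPP2-labelled WT libraries, Cd48 changed by 4.03 ± 0.35, Cd34 by 2.39 ± 0.19, Il7r by 4.50 ± 0.39, Fcgr3 by 3.40 ± 0.69, Slamf1 by -3.21 ± 0.39, Procr by -2.37 ± 0.39 and Kit by -0.31 ± 0.08, and Ly6a was not called (0.12 ± 0.24). Nupr1 fell to 3.24 ± 2.96 CPM, from 161 ± 11.3 in HSC. In this comparison 2576 of 21964 tested genes rose and 1619 fell, and after subtraction there were 1217 rises and 734 falls among 18532 genes. The split was 2133 rises and 1856 falls with median-of-ratios size factors and 2449 rises and 2293 falls with DESeq2, and it turned with genes of at least 20 CPM (1415 rises and 1892 falls).

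In the WT libraries labelled MPP4, stem cell identity genes were lower than in HSC: 20 of 27 measured genes fell and 7 were not called, with 25 falls adjusted over the list alone and 17 after background subtraction (camera, adjusted p = 7.86e-25). Hlf, a transcription factor of stem cells, was 5.36-fold lower (log2 fold change -2.42 ± 0.07, SE, n = 3 against 3, adjusted p = 1.25e-29, edgeR), and Mecom and Meis1 changed by -1.60 ± 0.06 and -1.15 ± 0.06. Of genes of G2 and mitosis, 21 of 30 measured genes rose and 9 were not called, with 25 rises adjusted over the list alone and 22 after background subtraction (adjusted p = 4.87e-21). Mki67 was at 1.21 ± 0.07 and Top2a at 1.37 ± 0.14. Of erythroid genes, 14 of 23 measured genes rose, 1 fell and 8 were not called, against 15 and 1 adjusted over the list alone and 13 and 0 after background subtraction (adjusted p = 3.91e-16). Car1 was at 3.70 ± 0.20 and Aqp1 at 2.53 ± 0.31. Of mast cell, basophil and eosinophil markers, 5 of 14 measured genes rose and 9 were not called, with 6 rises adjusted over the list alone and 3 after background subtraction (adjusted p = 3.55e-05). Il1rl1 was at 3.30 ± 0.24, Ms4a2 at 2.96 ± 0.56 and Cpa3 at 1.61 ± 0.33. Of megakaryocyte and platelet genes, 2 of 19 measured genes rose, 5 fell and 12 were not called, against 2 and 5 adjusted over the list alone and 2 and 3 after background subtraction, and the list was not past the threshold (adjusted p = 0.105 by camera). By fry, which asks whether the members move one way on balance, its adjusted p was 2.18e-04. Its member Fli1 changed by -0.95 ± 0.06.

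Of the sort markers in the MPP4-labelled WT libraries, Procr changed by -3.76 ± 0.43, Cd48 by 2.83 ± 0.34, Il7r by 3.25 ± 0.39, Ly6a by -1.06 ± 0.25 and Kit by -0.55 ± 0.08. Flt3, Cd34, Slamf1 and Fcgr3 were not called against HSC (log2 fold changes of 0.04 ± 0.12, -0.04 ± 0.20, -0.83 ± 0.33 and 1.98 ± 0.68). Fcgr3 was called there with median-of-ratios size factors, with DESeq2, with a filter of at least 5 CPM and without WT HSC replicate 1 or MPP4-labelled replicate 2 (adjusted p = 0.0396, 0.00968, 0.0451, 0.0443 and 0.0416). Like Fcgr3, Slamf1 was called with an assumed coefficient of variation of 0.2, and also without a filter, with limma-voom and in a fit of the 6 libraries alone (0.00389, 0.0203 and 0.0161), and in that fit Ly6a lost its call (0.0562). In this comparison 640 of 21964 tested genes rose and 1633 fell, and after subtraction there were 813 rises and 1309 falls among 18532 genes. Rises were 28.2% of the calls as deposited, 44.6% with median-of-ratios size factors (999 against 1241) and 47.4% with DESeq2 (1336 against 1482), and the median of all genes was 0.05 under the first and 0.17 under the second.

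**Figure D3:**
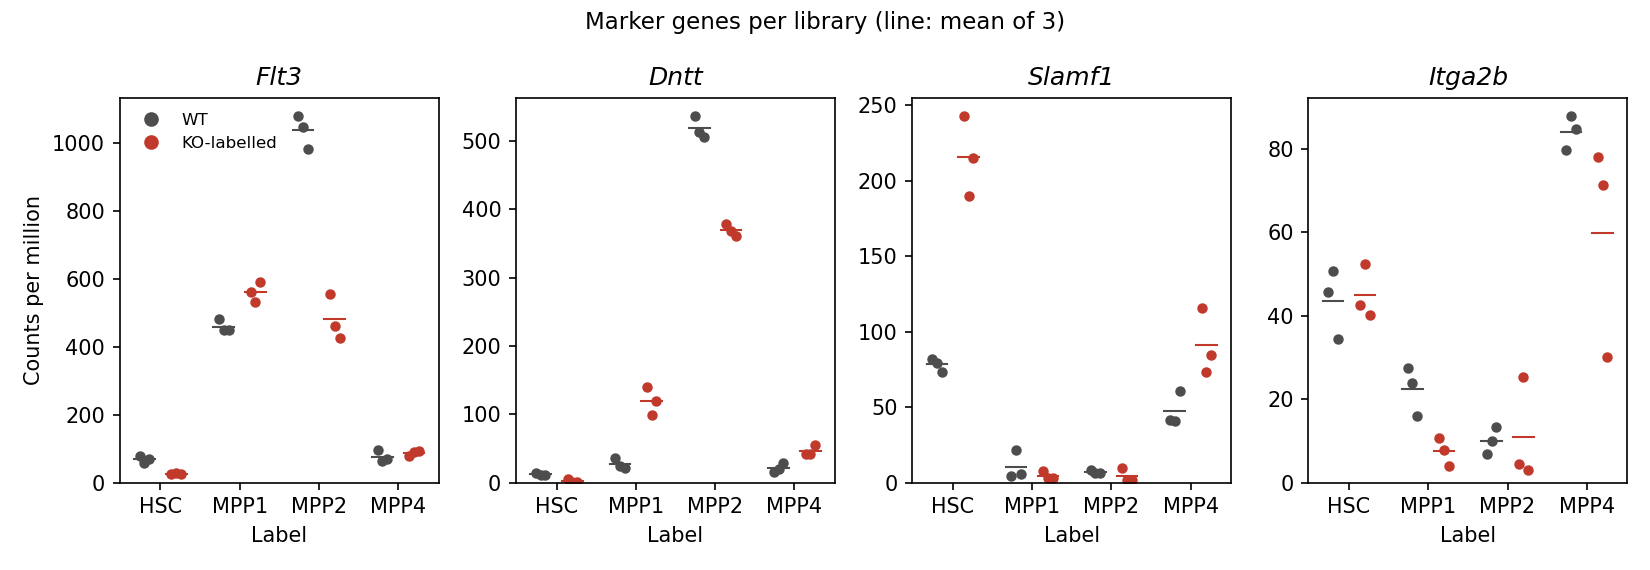
CPM of the unscaled library total (y axis) for 4 marker genes in each of the 24 libraries, by label and genotype. Points are libraries and lines the mean of 3. Flt3 and Dntt were higher in the MPP2-labelled libraries than in the MPP4-labelled ones, and Slamf1 and Itga2b lower, in both genotypes.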

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

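Of the tests in this part, the comparison of background density on X and autosomes was chosen after the result was seen.

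The difference between KO-labelled and WT libraries itself differed between the 4 populations for 3881 genes (edgeR interaction test). The lowest adjusted p-values were those of the V segment Ighv5-16 (1.5e-26), of Mpo (1.43e-23), of the kinase gene Prkg1 (2.12e-22) and of the V segment Igkv15-103 (9.73e-22). Next came Inpp4b (5.59e-20), Auts2 (1.26e-19), Ighm (1.26e-19) and Lrmda (6.17e-19). In Prkg1 the log2 fold change was 0.46 ± 0.08 in HSC, -1.75 ± 0.08 in MPP1, -2.19 ± 0.08 in MPP2-labelled and -0.61 ± 0.08 in MPP4-labelled libraries (SE, n = 3 against 3). The background expected from gene span made up 38.6% of the WT count of Inpp4b, 33.0% of that of Auts2, 19.3% of that of Prkg1 and 7.70% of that of Lrmda, all of them long genes, and after background subtraction all 4 were still called (adjusted p = 1.93e-10, 9.19e-12, 9.01e-09 and 1.4e-09).

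Genes of low abundance were lower in the KO-labelled libraries of all 4 populations, most so in HSC. A lower depth of these libraries is argued against: with every library thinned to the smallest total, the WT library with the fewest genes detected had 457 more than any KO-labelled library. Genomic DNA counted over gene spans is a candidate source. Silent genes on X had 0.458 times the counts per kb of silent autosomal genes in the 12 WT libraries (0.417 to 0.506 over resamples of the genes). A single X gives 0.5. The silent genes were chosen for few counts per kb in KO-labelled HSC, so the ratios of those libraries, up to 0.711, are shaped by that choice. Outside HSC, single KO-labelled libraries ran from 0.416 to 0.666, highest in MPP2-labelled libraries, which a single X alone does not give. A background set by the library stays open for genes outside the receptor families: where mostly background, their median change in HSC differed from the log2 ratio of receptor density (-1.68) by -0.20 as fitted but by 0.30 with groups of at most 3 counts set to 3, at the limit of 0.3 set beforehand and by less in the other populations, so the test does not decide in HSC, where 1302 of 4092 such genes had a group near 0 (their summed CPM gave -1.68). A general fall of weakly expressed genes, by the 0.3 set beforehand in every population, stays undecided for those with little background. Their median minus that of genes above 64 CPM was -0.29 in MPP2-labelled libraries (-0.36 to -0.24 over resamples, on both sides of that limit). It was -0.52, -0.61 and -0.37 in HSC, MPP1 and MPP4-labelled libraries, so they were lower relative to abundant genes in all 4. Their own median change was 0.014, -0.33, -0.22 and -0.016 in HSC, MPP1, MPP2-labelled and MPP4-labelled libraries. In HSC and MPP4-labelled libraries the gap thus went with a higher median of abundant genes (0.53 and 0.35).

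With 3 libraries against 3 there are 10 splits, so a share of splits under 0.05 cannot be reached. The real split, 1 of the 10, gave 9462 called genes in HSC, 2988 in MPP1, 1735 in MPP2-labelled and 3926 in MPP4-labelled libraries, and the highest of the other splits gave 0, 0, 1 and 1. For WT MPP1, MPP2-labelled and MPP4-labelled libraries against HSC the real split gave 835, 4195 and 2273, and the highest other 0, 0 and 1. For the average over populations the real grouping gave 11689 genes, against 1310 at most in the others, and was 1 of 100 drawn with that many. For the interaction it gave 3881, again 1 of 100, against 3044. A chance assignment of these libraries to the genotypes is argued against for both. For the interaction the shuffles also broke up the difference between genotypes that the populations share. They therefore cannot tell whether that difference varied between populations. Because the 3 libraries of a group may come from 1 pool or animal, the shuffles cannot address chance differences between animals.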

How the results depend on the processing

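Background subtraction, the minimum of 20 CPM, the test of folds above 1.5, the assumed coefficient of variation and the sums of 3 libraries were chosen after seeing the data. Where a result of a named gene (365) or of a list described with the comparisons (51) was called as deposited or under an alternative, its sign was the same in both. Results called in neither could change sign, as Ddx6 did in HSC after background subtraction. Of 365 named gene results, 359 stayed on the same side of the threshold with median-of-ratios size factors and 360 without a filter, as did 329 of 331 with DESeq2 and 304 of 351 after background subtraction. Among 51 list results, the P-body list in MPP2-labelled libraries lost its call with median-of-ratios size factors, after background subtraction and without 5 of the 6 single libraries, and the stem cell identity list there with a prior count of 0.5, with the block and without 3 of them. A call was lost in 68 of 357 named gene results with the test of folds above 1.5 and in 107 of 3144 with a library left out, and in 4 of 49 list results with genes of at least 20 CPM, which were the P-body lists of HSC, MPP2-labelled and MPP4-labelled libraries and the interferon list of HSC. Background subtraction left 1597 called genes in HSC, 1119 in MPP1, 861 in MPP2-labelled and 1345 in MPP4-labelled libraries, 4373 in the average, 1129 in the interaction and 1951 in WT MPP2-labelled libraries against HSC. Of the calls in HSC as deposited, 822 rises and 664 falls were also called after it, and 7 in the opposite direction, as were 38 calls in the average, 1 in MPP4, 1 in WT MPP2 against HSC and 0 in each of the other comparisons. With only genes of at least 20 CPM, fewer genes were tested, and 3600 were called in HSC and 4562 in the average. A test of folds above 1.5, which asks for more, called 5588, 471, 378 and 588 genes in HSC, MPP1, MPP2 and MPP4, 4094 in the average and 111, 1188 and 691 in WT MPP1, MPP2 and MPP4 against HSC. An assumed coefficient of variation of 0.2, below the 0.393 estimated, called 7960, 5643 and 9600 in MPP1, MPP2 and MPP4, 11826 in the interaction and 3053, 9576 and 6263 in the WT comparisons. Sums of the 3 libraries of each group, 4 against 4, called 2146 in the average. The direction with more calls turned in fits besides those given with each comparison. With genes of at least 20 CPM it did in HSC (1819 rises, 1781 falls), MPP1 (1001 rises, 1582 falls), MPP4 (1003 rises, 1779 falls) and WT MPP4 against HSC (1327 rises, 1193 falls), and with the assumed variation in MPP1 (2823 rises, 5137 falls), MPP4 (3717 rises, 5883 falls) and WT MPP1, MPP2 and MPP4 against HSC (1347 rises, 1706 falls; 3440 rises, 6136 falls; 3266 rises, 2997 falls). In MPP2 it turned with limma-voom (1033 rises, 747 falls) and the 6 libraries alone (958 rises, 879 falls), and in WT MPP1 with limma-voom (503 rises, 703 falls), the 6 libraries alone (552 rises, 628 falls), no filter (399 rises, 440 falls) and, narrowly, without WT HSC replicate 1.

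Lists past the threshold were 11 in HSC, 8 in MPP2, 13 in MPP4, 12 in the average and 15 in WT MPP2 against HSC with genes of at least 20 CPM, against 24, 17, 24, 21 and 26, and 11 in MPP1 with an estimated correlation, against 17; the cause was not tested. With each library left out in turn, called genes ran from 7883 to 8193 in HSC, 2122 to 2338 in MPP1, 1117 to 1440 in MPP2, 3062 to 3521 in MPP4, 11009 to 11729 in the average, 3348 to 4027 in the interaction and 583 to 666, 3260 to 3521 and 1881 to 1959 in the WT comparisons, and lists from 24 to 25, 15 to 18, 14 to 17, 22 to 24 and 20 to 22 and, for WT, 14 to 15, 24 to 26 and 15 to 18. Without WT MPP2 replicate 3, 1117 genes were called in MPP2 in place of 1735. With the replicate number as a block, 8690, 2860, 1607 and 3718 genes were called in the 4 populations, 11206 in the average, 3600 in the interaction and 811, 4115 and 2236 in the WT comparisons, and 24, 16, 16, 23 and 22 lists in the populations and the average. The numbers did not pair the libraries: deviations of same-numbered WT and KO-labelled libraries correlated across genes by -0.00480 to 0.0163 in 12 pairs, and those of populations of one genotype by -0.0168 to 0.0260 in 36 pairs. At this depth and spread, with 3 libraries per group, 5 of 100 genes changed 1.5-fold were recovered in the simulation for HSC (5 of 37 at 20 CPM or more), and which of these limits recovery was not tested. Only 200 genes and a list of 23 were changed there, against 9462 called in the real HSC comparison. The Benjamini-Hochberg adjustment is stricter where fewer genes change, so this recovery is not that of the real comparison.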

Other observations

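The tests on V genes and on the labels MPP2 and MPP4 in this part were chosen after the result was seen.

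Translation factors, which start and lengthen protein chains, were higher in KO-labelled HSC and MPP4-labelled libraries: 33 of 42 rose and 0 fell (35 and 0 adjusted over the list alone, 6 and 1 after background subtraction) in HSC, and 22 of 42 rose and 0 fell (25 and 0 adjusted over the list alone, 3 and 1 after background subtraction) in MPP4-labelled libraries (camera, adjusted p = 1.93e-12 and 4.35e-09). Of heat shock genes, chaperones of protein folding, 9 of 15 rose and 0 fell (9 and 0 adjusted over the list alone, 4 and 0 after background subtraction) in HSC (adjusted p = 1.86e-05). Autophagy and lysosome genes were higher in HSC, where 16 of 37 rose and 1 fell (16 and 1 adjusted over the list alone, 1 and 1 after background subtraction), and in MPP4-labelled libraries, where 14 of 37 rose and 0 fell (15 and 0 adjusted over the list alone, 4 and 0 after background subtraction) (adjusted p = 1.18e-04 and 7.11e-06). In HSC the autophagy call was lost after background subtraction (adjusted p = 0.0798). Of mitochondrially encoded proteins in HSC, 7 of 11 rose and 0 fell (7 and 0 adjusted over the list alone, 3 and 0 after background subtraction). That list had an adjusted p = 6.7e-06 by camera and an adjusted p = 0.0951 with an estimated correlation. Of chromatin regulators in MPP1, 34 of 63 rose and 1 fell (37 and 1 adjusted over the list alone, 15 and 1 after background subtraction), and in MPP4-labelled libraries 38 of 63 rose and 0 fell (47 and 0 adjusted over the list alone, 11 and 0 after background subtraction) (adjusted p = 1.22e-14 and 4.87e-14).

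Interferon response genes were higher in KO-labelled MPP1, where 10 of 37 rose and 0 fell (11 and 0 adjusted over the list alone, 4 and 0 after background subtraction) (camera, adjusted p = 3.47e-05), and not past the threshold in MPP2-labelled libraries, where 1 of 37 rose and 3 fell (1 and 3 adjusted over the list alone, 1 and 3 after background subtraction) (adjusted p = 0.072). After background subtraction the list was lower there (adjusted p = 0.00722). Genes of replication-dependent histones, whose near-identical copies make counts per gene uncertain, went in different directions: in HSC 12 of 36 rose and 0 fell (11 and 0 adjusted over the list alone, 2 and 0 after background subtraction), and in MPP2-labelled libraries 0 of 36 rose and 4 fell (0 and 6 adjusted over the list alone, 0 and 4 after background subtraction) (adjusted p = 6.7e-06 and 2.01e-04). Of S phase genes in MPP4-labelled libraries, 9 of 29 rose and 0 fell (11 and 0 adjusted over the list alone, 2 and 0 after background subtraction) (adjusted p = 7.11e-06). Of erythroid genes in HSC, 4 of 23 rose and 9 fell (4 and 9 adjusted over the list alone, 1 and 9 after background subtraction), with no call by camera (adjusted p = 0.494) and a fall by fry (adjusted p = 1.41e-06) and by camera after background subtraction (adjusted p = 0.00529). Of mature neutrophil and monocyte markers in HSC, 0 of 15 rose and 8 fell (0 and 8 adjusted over the list alone, 0 and 0 after background subtraction) (adjusted p = 0.0232), a call lost after subtraction (adjusted p = 0.0572). Whether list changes differed between populations was not tested.

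Immunoglobulin V genes were shared by the 3 libraries of a group: their usage correlated across V genes by 0.928 to 0.986 between libraries of a group and by -0.190 to 0.408 between libraries of different groups, and 40 of 57 such genes reached 50 counts in 1 group only. Cells of separate animals cannot be told apart from a shared pool, although the highest correlation between groups, 0.408, lay below the lowest within a group, because usage set by population and genotype together would give the same, and rearrangement itself is not seen in counts per gene. The 3 libraries of a group made from 1 pool of cells, or from 1 animal, is a candidate explanation, with 0.928 as the lowest correlation within a group. The test covers the 4 groups with at least 5 such genes, and V genes are not independent replicates. If a single pool or animal holds, the spread between libraries would leave out the spread between animals, and p-values would be too small as tests of genotype.

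The MPP2-labelled libraries had more RNA of lymphoid genes and less of megakaryocyte genes than the MPP4-labelled libraries. In WT, Flt3 was 17.5-fold higher (log2 difference 4.13 ± 0.13, adjusted p = 4.17e-27, edgeR) and Dntt higher by 4.99 ± 0.24, while Slamf1 and Itga2b differed by -2.38 ± 0.39 and -2.71 ± 0.43, and in KO-labelled libraries the differences were 2.68 ± 0.12, 3.24 ± 0.21, -4.23 ± 0.43 and -2.17 ± 0.43, of which Slamf1 was at -5.63 without MPP2-labelled replicate 1 and Itga2b at -3.76 without replicate 2. An exchange of labels in 1 genotype only is argued against, because the megakaryocyte list went the same way in both, with medians of -1.37 in WT and -1.10 in KO-labelled libraries (-1.08 with groups of at most 3 counts set to 3). Labels MPP2 and MPP4 exchanged in both genotypes may explain the pattern, as MPP4 is usually the lymphoid-biased population, and the smaller of the medians of the lymphoid list was 1.10 (1.70 in WT). Sort gates drawn otherwise than usual stay open and were not tested, as does a biological difference; if the labels were exchanged, the KO-labelled against WT comparisons would keep their libraries and only their names would change.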
